A study of Mus musculus with 24 samples.

How the data were processed

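RNA sequencing libraries came from cultured bone marrow-derived macrophages of mice, with 3 libraries in each of 8 groups: WT and KO cells, each untreated, or given LPS, IFNg or IL4. The labels do not state whether replicates came from separate animals or cultures, so the p-values measure only the spread between these samples. The deposited table held a signal, which the authors had made by scaling gene-level read counts with 1 factor per library. This was read from the values: in each library every value was a whole multiple of that library's smallest step within a tolerance of 0.05 reads, and median-of-ratios factors computed from the recovered whole reads matched the deposited factors to 6.95e-10 percent. Alignment to mouse build mm10 (GRCm38) was credited to TopHat2 2.2.1 per the submitters' processing notes, which also name Cufflinks 2.2.1 and Cuffdiff. The table held 43629 gene identifiers, of which 24301 had a read in any library. Positions came from the GENCODE M21 annotation of GRCm38, which held 42462 of the identifiers, with coordinates counted from 1.

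Recovered reads per library ranged from 1478507 to 73409343 (median 29551522; 26037890 in KO and 31633594 in WT libraries), and genes with at least 1 read from 11223 to 18418. Sums of the deposited values ranged from 18992840 to 37512449. The value of a single read, and with it the limit of detection, differed between libraries: a floor of 3 reads was 70.9 in KO LPS replicate 1. Intervals and floors cover counting error only. The 10 most abundant genes held 9.60% to 16.0% of reads. No library duplicated another: between libraries of the same group, the chi-square per degree of freedom of their reads ranged from 2.08 to 26.6 over 24 pairs.

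Values were analysed as log2 of the value plus 1. Genes with a value of at least 1 in at least 3 libraries were kept, 18637 in all. A linear model with 1 mean per group was fitted to all 24 libraries with limma 3.58.1 in R 4.3.3 (moderated statistics with a mean-variance trend, 16 residual degrees of freedom), and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. The 11 comparisons were KO against WT in each treatment and averaged over the treatments, each treatment against control in WT, and the interaction of genotype with each treatment. These comparisons, the thresholds, the gene lists, the naming rule and the alternatives not marked as later additions were chosen before the data were examined.

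Genes named in the text followed a rule. Cited2 and Lyz2 were named in every group. For each comparison of genotypes, the 8 largest rises and 8 largest falls were taken among called genes whose genotypes did not overlap and whose mean was at least 1 in either genotype (for the average, with the same sign in all 4 treatments). For each treatment in WT, the 5 largest rises and falls were taken with preset markers (Il6, Il1b, Nos2 and Tnf for LPS, Cxcl9, Gbp2, Irf1 and Ciita for IFNg, Arg1, Retnla, Chil3 and Mrc1 for IL4), which were also followed between genotypes. For each interaction, the 5 largest called genes of either sign were taken, and from each list up to 4 members with the smallest p. Predicted genes, pseudogenes, microRNA and small nucleolar RNA genes were left out of all but the lists. Not every gene of the rule is named, and gene families, Trim30d with LPS and the immunoglobulin genes as a class were chosen after their values were seen. A fold against a group without a read was computed against 3 reads over that group and is a lower bound.

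Gene lists covered inflammatory, type I interferon, interferon-gamma, IL-4 alternative activation, HIF-1 and glycolysis, PPARg, LXR and lipid, cholesterol, cell cycle, unfolded protein, lysosome, oxidative phosphorylation, macrophage identity, immediate early, NRF2 and CITED partner genes. They also covered markers of neutrophils, monocytes, dendritic cells, T and NK cells, B cells, fibroblasts, mast cells and erythroid cells, sex-linked and mitochondrially encoded genes, and genes next to Cited2. Of 26 lists 25 were tested; the erythroid list was left out because 2 of its 12 genes were measured and at least 5 were required. Each list was tested with camera of limma (two-sided, inter-gene correlation 0.01), and again with an estimated correlation, adjusted over the lists of a comparison. The adjusted p of a list is that at the preset correlation of 0.01 unless the estimated one is named. That preset treats members as nearly uncorrelated, so very small values can overstate the evidence where members move together. Members were counted as raised or lowered over all genes tested and adjusted over the list alone. The fry test was run as a check of whether members moved, without comparison to other genes.

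Genes changed by a treatment (adjusted p below 0.05 and an absolute log2 change of at least 1, averaged over genotypes) were compared between genotypes by their median log2 difference, with 10000 random gene sets matched in 10 bins of expression as a description. That average and the comparison of genotypes within the treatment are uncorrelated only where libraries of both genotypes vary equally. Principal components used genes with a mean log2 value of at least 6.

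Alternatives were a pseudocount of 0.1, no filter, a filter at a value of 5, a replicate block, quantile normalization, median centring, a fit of only the compared groups, an absolute log2 fold change of at least 1, a log2 change of at least 2 for treatment-changed genes, and leaving out each replicate. Chosen after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, limma with library weights, edgeR without KO LPS replicate 1, lists and named genes without that library, and treatment-lowered genes without each library. The procedure was tested on simulated data made from these libraries, with 200 changed genes per comparison, 100 at each of 2 sizes. The changed genes were drawn only from those above a minimum mean value.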

Results

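The series profiled gene expression by RNA sequencing in bone marrow-derived macrophages (BMDMs), macrophages grown in culture from bone marrow precursors, of C57BL/6 mice. Cells were wild type (WT) or lacked CITED2 (KO), a transcriptional co-regulator that binds the coactivators CBP and p300. Each genotype was left untreated (control) or given lipopolysaccharide (LPS), a bacterial cell wall component that activates macrophages through a Toll-like receptor, interferon gamma (IFNg), the cytokine of classical activation, or interleukin 4 (IL4), the cytokine of alternative activation. The 8 groups held 3 libraries each, 24 in all. The values were normalised read counts, and the reads behind them ranged from 1478507 in KO LPS replicate 1 to 73409343 in WT IFNg replicate 3, with a median of 29551522 per library. After KO LPS replicate 1, the shallowest libraries were WT control replicate 3 with 7818719, WT LPS replicate 1 with 7921412 and KO IFNg replicate 1 with 15893968 reads. In KO LPS replicate 1 a single read equalled 23.6 in value, and 7441 of the 18637 genes tested had no read there, against 2318 in the median library. On the first principal component, which held 72.3% of the variance of 9570 genes, LPS and IFNg libraries lay apart from control and IL4 libraries. KO LPS replicate 1 stood apart on the fourth component (3.69% of the variance), at -57.1 where the other KO LPS libraries lay at 3.24 and 3.93.

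Cited2 itself (ENSMUSG00000039910; GRCm38 chromosome 10, 17723218 to 17725674, plus strand, protein coding) was nearly absent from every KO group. Its normalised read count in control cells was 27.9 ± 10.4 in KO and 2207 ± 80.5 in WT (SD, n = 3 per group). Values carry the SD and log2 differences the SE of the fit, with 3 libraries per group. The KO level was 1.26% of WT in control, 1.35% with LPS (0.718% without KO LPS replicate 1), 0.558% with IFNg and 1.02% with IL4. Averaged over the 4 treatments the log2 difference was -6.68 ± 0.17 with 12 libraries per genotype and an adjusted p of 2.8e-19. Within WT cells, Cited2 was 3593 ± 529 with LPS, 2438 ± 165 with IFNg and 1148 ± 51.0 with IL4. Its log2 difference from control was 0.69 with LPS (adjusted p = 0.088, range over the alternatives 5.5e-09 to 0.85), 0.14 with IFNg (adjusted p = 0.79) and -0.94 with IL4 (adjusted p = 0.05, range over the alternatives 1.8e-11 to 0.12). The call with IL4 ended when any 1 of the 6 compared libraries was left out. Lyz2 (ENSMUSG00000069516; chromosome 10, 117277331 to 117282321, minus strand), which encodes lysozyme and is a common insertion site for Cre recombinase in myeloid cells, was at 52.2% of WT in KO control cells, 56.7% with LPS, 61.4% with IFNg and 76.8% with IL4. Averaged over the treatments its log2 difference was -0.71 ± 0.04 (adjusted p = 1.6e-13). The labels do not state how the gene was deleted.

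**Figure D1:**
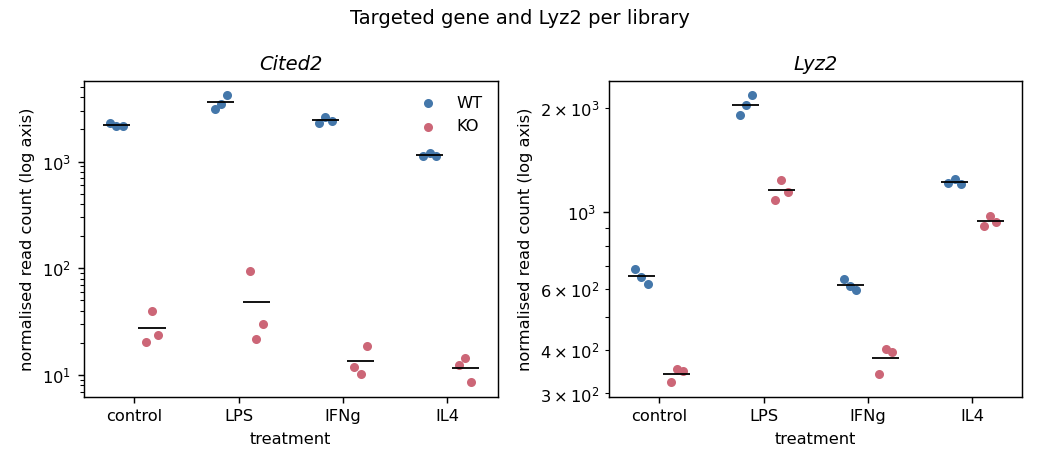
Normalised read counts of Cited2 and Lyz2 in each of the 24 libraries (points, log axis) by treatment and genotype, with bars at the mean of 3 libraries. Cited2 in control cells averaged 2207 in WT and 27.9 in KO.

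The response of WT cells to LPS gives the background for the genotype comparisons. Prostaglandin synthase Ptgs2 went from 25.3 ± 20.4 in control to 129723 ± 11177 with LPS, a log2 rise of 12.53 ± 0.26. Il12b, a subunit of interleukin 12, rose by 12.51 ± 0.48 on the log2 scale, the vasoconstrictor peptide gene Edn1 by 12.26 ± 0.39 and the chemokine gene Cxcl10 by 11.91 ± 0.22. The cytokine genes Il6, Il1b and Tnf rose by 11.38 ± 0.48, 11.87 ± 0.32 and 8.68 ± 0.09, and Nos2, the inducible nitric oxide synthase, by 11.63 ± 0.27, with adjusted p of at most 2.8e-16. Of the 39 measured inflammatory cytokines, chemokines and NF-kB targets, 38 rose (39 adjusted over the list alone, median log2 8.68, adjusted p = 7.0e-31). All 36 type I interferon and antiviral genes rose (36 adjusted over the list alone, median 5.05, adjusted p = 1.7e-36), as did all 42 interferon-gamma genes (42 adjusted over the list alone, median 4.46, adjusted p = 2.4e-28). Among HIF-1 and glycolysis genes, 24 of 37 rose and 7 fell (the same counts adjusted over the list alone, adjusted p = 2.3e-04), for instance the glycolytic regulator Pfkfb3, 24795 ± 412 with LPS and 815 ± 32.5 in control.
PPARg, LXR and lipid handling genes went the other way, with 19 of 30 lowered and 7 raised (the same counts adjusted over the list alone, adjusted p = 0.022, or adjusted p = 0.2 with an estimated correlation). Among them the nuclear receptor gene Pparg fell from 1848 ± 51.2 to 148 ± 5.43. The largest falls by the naming rule were in Fam214a (-7.62 ± 0.22), Arhgap19 (-7.43 ± 0.12) and the cannabinoid receptor gene Cnr2 (-7.40 ± 0.37). In all, 4759 genes rose and 5183 fell.

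With IFNg, WT cells raised the chemokine gene Cxcl9, 361511 ± 19295 with IFNg and 36.2 ± 3.88 in control, a log2 rise of 13.25 ± 0.30. Serpina3g rose by 12.35 ± 0.32, Il12b by 11.63 ± 0.48, and the interferon-inducible GTPase genes Tgtp1 and Gbp4 by 11.25 ± 0.45 and 11.24 ± 0.26. Gbp2, the transcription factor gene Irf1 and Ciita, the master regulator of MHC class II, rose by 9.76 ± 0.10, 5.21 ± 0.06 and 6.52 ± 0.09. All 42 interferon-gamma genes rose (42 adjusted over the list alone, median 5.07, adjusted p = 2.4e-43), as did all 36 type I interferon genes (36 adjusted over the list alone, median 3.23, adjusted p = 2.6e-36). Of the inflammatory genes 32 of 39 rose and 3 fell (32 and 3 adjusted over the list alone, adjusted p = 5.8e-17). PPARg, LXR and lipid handling genes fell in 21 of 30 cases and rose in 5 (the same counts adjusted over the list alone, adjusted p = 2.8e-04), among them Plin2, a lipid droplet coat gene (-1.93 ± 0.05), and Fabp4 (-1.92 ± 0.06). The Wnt antagonist gene Dkk2 fell by 7.11, with values of 2.16 ± 2.01 with IFNg and 358 ± 29.3 in control. In all, 4201 genes rose and 4211 fell.

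IL4 raised Arg1 in WT cells, which encodes arginase 1 and marks alternative activation (ENSMUSG00000019987; chromosome 10, 24915221 to 24927484), from 2.75 ± 0.424 to 3841 ± 276, a log2 rise of 10.00 ± 0.47. Retnla, another marker, had no read in the WT control libraries and 207 ± 8.27 with IL4, at least 264-fold higher when the control is set at 3 reads over the group. Chil3 and the mannose receptor gene Mrc1 rose by 4.97 ± 0.10 and 1.95 ± 0.08, and Pdcd1lg2, the PD-1 ligand gene, by 7.98 ± 0.63. Of 33 IL-4 alternative activation genes 28 rose and 5 did not pass (28 raised adjusted over the list alone, median 2.63, adjusted p = 1.7e-41). Mitochondrial oxidative phosphorylation genes rose by smaller steps, in 29 of 36 cases (31 adjusted over the list alone, median 0.41, adjusted p = 1.9e-16), such as the ATP synthase subunit gene Atp5b (0.61 ± 0.04). Unfolded protein response genes rose in 15 of 25 cases and fell in 2 (15 and 3 adjusted over the list alone, adjusted p = 1.0e-07). Cholesterol biosynthesis genes rose in 8 of 24 (11 adjusted over the list alone, adjusted p = 3.8e-05). Ifitm6 (-3.89 ± 0.19), Dkk2 (-3.85 ± 0.41) and Ighm, the immunoglobulin mu chain gene (-3.71 ± 0.19), fell most by the naming rule. Neutrophil and granulocyte precursor markers fell in 7 of 16 cases and rose in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.017, or adjusted p = 0.14 with an estimated correlation). In all, 1967 genes rose and 1782 fell, and with library weights 6125 genes passed.

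**Figure D2:**
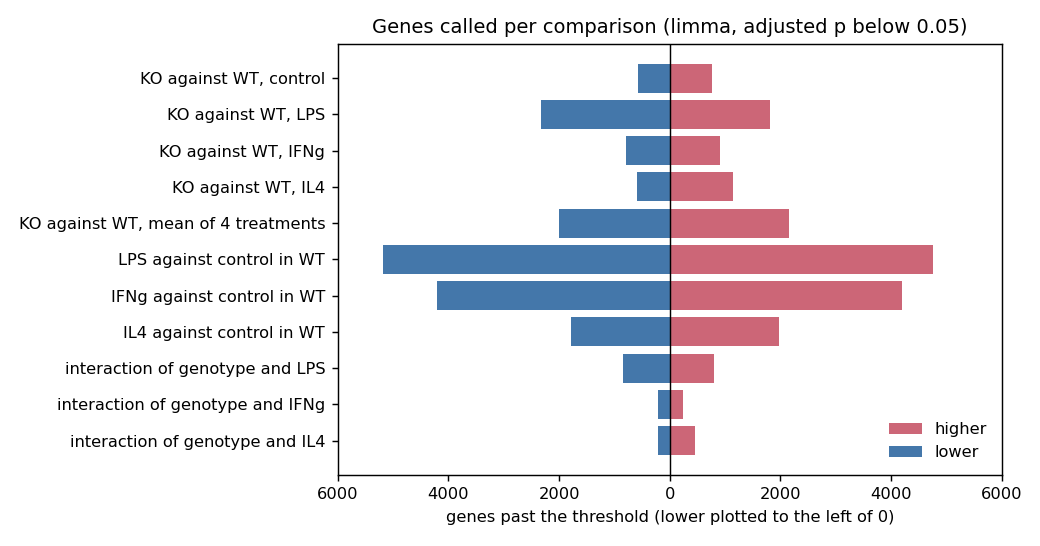
Number of genes raised (right of 0) and lowered (left of 0) in each of the 11 comparisons of the limma fit to all 24 libraries. LPS changed 9942 genes in WT cells, and the genotypes differed in 4141 genes with LPS.

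Without treatment, loss of CITED2 went with a rise of the histidine-degrading enzyme genes Hal and Amdhd1 and with lower levels of a group of Trim genes. Hal (ENSMUSG00000020017; chromosome 10, 93488768 to 93519304) was 1896 ± 89.3 in KO and 10.3 ± 2.62 in WT, a log2 difference of 7.42 ± 0.32 (adjusted p = 4.7e-14). Its neighbour Amdhd1 (chromosome 10, 93523338 to 93540033) was 15.8 ± 2.39 in KO and 0.395 ± 0.346 in WT. Trim12a (ENSMUSG00000066258; chromosome 7, 104299894 to 104315466), of the antiviral tripartite motif family, was 0.641 ± 0.561 in KO and 428 ± 48.3 in WT (log2 -8.09 ± 0.86, adjusted p = 3.7e-07). Its relatives Trim5 and Trim30d differed by -5.75 ± 0.44 and -4.75 ± 0.23. Of 12 Trim genes in this part of chromosome 7, 5 were lower and 2 higher in KO, among the latter Trim34b (log2 3.07, adjusted p = 0.0037). Gvin1, an interferon-inducible GTPase gene of the same chromosome (106156556 to 106215326), had no read in KO and 13.5 ± 7.54 in WT, at least 16.8-fold lower with KO set at 3 reads over the group. Immunoglobulin gene segments were higher in KO, 79 of 183 measured, with Ighv3-6 at 47.5 ± 4.45 in KO and 1.51 ± 1.63 in WT. The exception was Ighm, 96.0 ± 5.33 in KO and 958 ± 55.9 in WT (log2 -3.31 ± 0.19).

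Several macrophage programmes were lower in untreated KO cells. Of 39 inflammatory genes 12 fell and 2 rose (15 and 4 adjusted over the list alone, median -0.31, adjusted p = 1.5e-05). Among these Nlrp3, the inflammasome sensor gene, was 231 ± 4.71 in KO and 486 ± 13 in WT (log2 -1.07 ± 0.06), and Tnf was 122 ± 18.7 in KO and 192 ± 30.2 in WT (log2 -0.66 ± 0.09). Cholesterol biosynthesis genes fell in 7 of 24 cases, with 17 not past (12 lowered adjusted over the list alone, median -0.23, adjusted p = 5.6e-08). Macrophage identity genes fell in 10 of 29 cases and rose in 4 (15 and 5 adjusted over the list alone, adjusted p = 3.9e-06), among them the monocyte chemokine receptor gene Ccr2 (-1.66 ± 0.15) and the transcription factor gene Maf (-0.80 ± 0.06).
Lysosome and autophagy genes rose in 9 of 30 cases (13 adjusted over the list alone, median 0.10, adjusted p = 7.3e-05), a call lost at adjusted p = 0.093 with an estimated correlation. PPARg, LXR and lipid handling genes rose in 8 and fell in 5 of 30 cases (10 and 5 adjusted over the list alone, adjusted p = 0.0032, or adjusted p = 0.093 with an estimated correlation). Plin2 was 43422 ± 2201 in KO and 29327 ± 529 in WT. The C-type lectin gene Clec7a (Dectin-1) was 21912 ± 1689 in KO and 9056 ± 358 in WT (log2 1.27 ± 0.07). In all, 766 genes were higher and 568 lower in KO. With library weights 3063 genes passed.

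With LPS, more inflammatory and interferon genes were called higher than lower in KO cells, though the list calls ended with an estimated correlation. Tnf (ENSMUSG00000024401; chromosome 17, 35199381 to 35202007) was 139998 ± 7023 in KO and 78574 ± 2179.7 in WT, a log2 difference of 0.83 ± 0.09 (adjusted p = 1.7e-07). Il6 (ENSMUSG00000025746; chromosome 5, 30013114 to 30019981) was 30559 ± 2896 in KO and 10719.7 ± 689.8 in WT (log2 1.51 ± 0.48, adjusted p = 0.026). Il1a differed by 1.43 ± 0.15 and Il23a, an interleukin 23 subunit gene, by 3.72 ± 0.39, whereas the prostaglandin E synthase gene Ptges differed by -2.55 ± 0.24. Il1b was 118193 ± 9755 in KO and 79159 ± 892 in WT and Nos2 80161 ± 4195 in KO and 60164 ± 4787 in WT. Neither passed, with adjusted p of 0.21 (range over the alternatives 2.4e-06 to 0.66) and 0.29 (range 8.0e-07 to 0.75). For both genes each KO LPS value lay above each WT LPS value. Their spread in the fit came from all groups, and control libraries held only 9 to 31 reads of Il1b and 6 to 26 of Nos2. The call of Il6 ended under 5 of 17 alternatives (adjusted p from 7.8e-78 to 0.31), among them leaving out WT LPS replicate 1 (adjusted p = 0.071), WT LPS replicate 2 (adjusted p = 0.074) or KO LPS replicate 2 (adjusted p = 0.058). Of 39 inflammatory genes 14 were higher and 5 lower in KO (16 and 6 adjusted over the list alone, median 0.32, adjusted p = 0.0025, or adjusted p = 0.1 with an estimated correlation).
Among type I interferon genes 20 of 36 were higher and 16 did not pass (23 higher adjusted over the list alone, median 0.32, adjusted p = 1.4e-13, or adjusted p = 0.079 with an estimated correlation), such as Cmpk2 (1.00 ± 0.08) and Oasl1 (1.20 ± 0.11). Of the interferon-gamma genes 21 of 42 were higher and 7 lower (24 and 8 adjusted over the list alone, median 0.46, adjusted p = 2.3e-07, or adjusted p = 0.079 with an estimated correlation). Irf8, a transcription factor gene of the macrophage lineage, was 32478 ± 1830.5 in KO and 7521 ± 209.7 in WT (log2 2.11 ± 0.05).

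The HIF-1 and glycolysis genes and the cholesterol genes were lower in LPS-treated KO cells. HIF-1 and glycolysis genes fell in 20 of 37 cases and rose in 2 (22 and 3 adjusted over the list alone, median -0.45, adjusted p = 2.9e-07). Examples were the angiogenic factor gene Vegfa, 463 ± 113 in KO and 1493 ± 123 in WT (log2 -1.71 ± 0.11), Bnip3 (-1.55 ± 0.12), Pfkfb3 (-0.68 ± 0.06) and the glycolytic enzyme gene Tpi1 (-0.83 ± 0.07). Of 24 cholesterol biosynthesis genes 16 fell and 2 rose (the same counts adjusted over the list alone, median -0.51, adjusted p = 9.2e-06), for instance Hsd17b7 (-0.88 ± 0.10) and Sc5d (-0.82 ± 0.10). Genes next to Cited2 fell in 6 of 11 cases (6 adjusted over the list alone, adjusted p = 0.0044, or adjusted p = 0.1 with an estimated correlation), Heca by 0.84. Arg1, low with LPS in both genotypes, was 1.24 ± 1.25 in KO and 34.1 ± 9.65 in WT. Trim12a and Gvin1 differed by -7.99 ± 0.86 and -8.39 ± 0.42, or -9.96 for Trim12a without KO LPS replicate 1, which held 8 reads of it, while Trim34b was 331 ± 41.5 in KO and 4.78 ± 5.48 in WT, and 70 of 183 immunoglobulin genes were higher.
In all, 1808 genes were higher and 2333 lower in KO. The balance turned under median centring (2198 and 2087), edgeR (1887 and 1656) and DESeq2 (1935 and 1646). Without KO LPS replicate 1, 2151 were higher and 1823 lower, 3118 of them called in the same direction as with it, and without KO LPS replicate 2 these counts were 1780 and 3258. Without replicate 1 the inflammatory genes had an adjusted p of 0.018, the type I interferon genes of 5.8e-12 and the HIF-1 and glycolysis genes of 8.4e-09. A fit of only the 6 LPS libraries called 1021 genes, and there the call of Trim12a ended (adjusted p = 0.077, range over the alternatives 5.9e-29 to 0.077).

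The LPS response itself differed by genotype. A positive interaction means that the log2 change from control had a higher value in KO than in WT, which is a smaller fall where the treatment lowers a gene. The rise of Tnf was larger in KO by 1.49 ± 0.13 on the log2 scale (adjusted p = 1.8e-08) and that of Nos2 by 1.57 ± 0.38 (adjusted p = 0.0081, range over the alternatives 1.2e-05 to 0.14). In control cells Nos2 averaged 7.58 in KO and 21.5 in WT, with 6 to 26 reads per library. Its interaction thus came in part from the lower untreated KO level, and its log2 difference with LPS, 0.42, did not pass. For Il6 the difference was 2.35 ± 0.68 (adjusted p = 0.03, range over the alternatives 0.0073 to 0.18), a size that depends on 0 to 4 reads of Il6 per control library. Of 23 alternatives 9 lost that call, among them leaving out WT control replicate 3, KO control replicate 1, WT LPS replicate 1 or WT LPS replicate 2, at adjusted p of 0.088, 0.1, 0.064 and 0.069. For Il1b the difference was 0.92 ± 0.45 (adjusted p = 0.24). Of the inflammatory genes 16 of 39 had a positive and 3 a negative interaction (20 and 4 adjusted over the list alone, median 0.64, adjusted p = 1.3e-08). HIF-1 and glycolysis genes had a negative interaction in 14 of 37 cases (19 adjusted over the list alone, median -0.37, adjusted p = 1.8e-07), such as Pfkfb3 (-1.04 ± 0.08) and the angiogenic factor gene Vegfa (-1.28 ± 0.15). Cell cycle genes, with a median change of -0.59 by LPS in WT, had a positive interaction in 5 of 35 cases (8 adjusted over the list alone, adjusted p = 0.0013). Type I interferon genes had 19 with a positive and 2 with a negative interaction (22 and 3 adjusted over the list alone, adjusted p = 3.8e-12, or adjusted p = 0.087 with an estimated correlation). Interferon-gamma genes had 12 and 2 of 42 (the same counts adjusted over the list alone, adjusted p = 1.8e-07, or adjusted p = 0.076 with an estimated correlation), Irf8 the former at 1.77 ± 0.08. Trim30d, lower in untreated KO cells, averaged 20214 in KO and 22573 in WT with LPS, an interaction of 4.60 ± 0.32.
The interaction was positive in 800 called genes and negative in 839 (968 and 739 under median centring). Without KO LPS replicate 1 these were 1026 and 881, and without KO LPS replicate 2 they were 787 and 1330. With library weights 2755 genes passed, and in a fit of only the 4 compared groups 862.

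**Figure D3:**
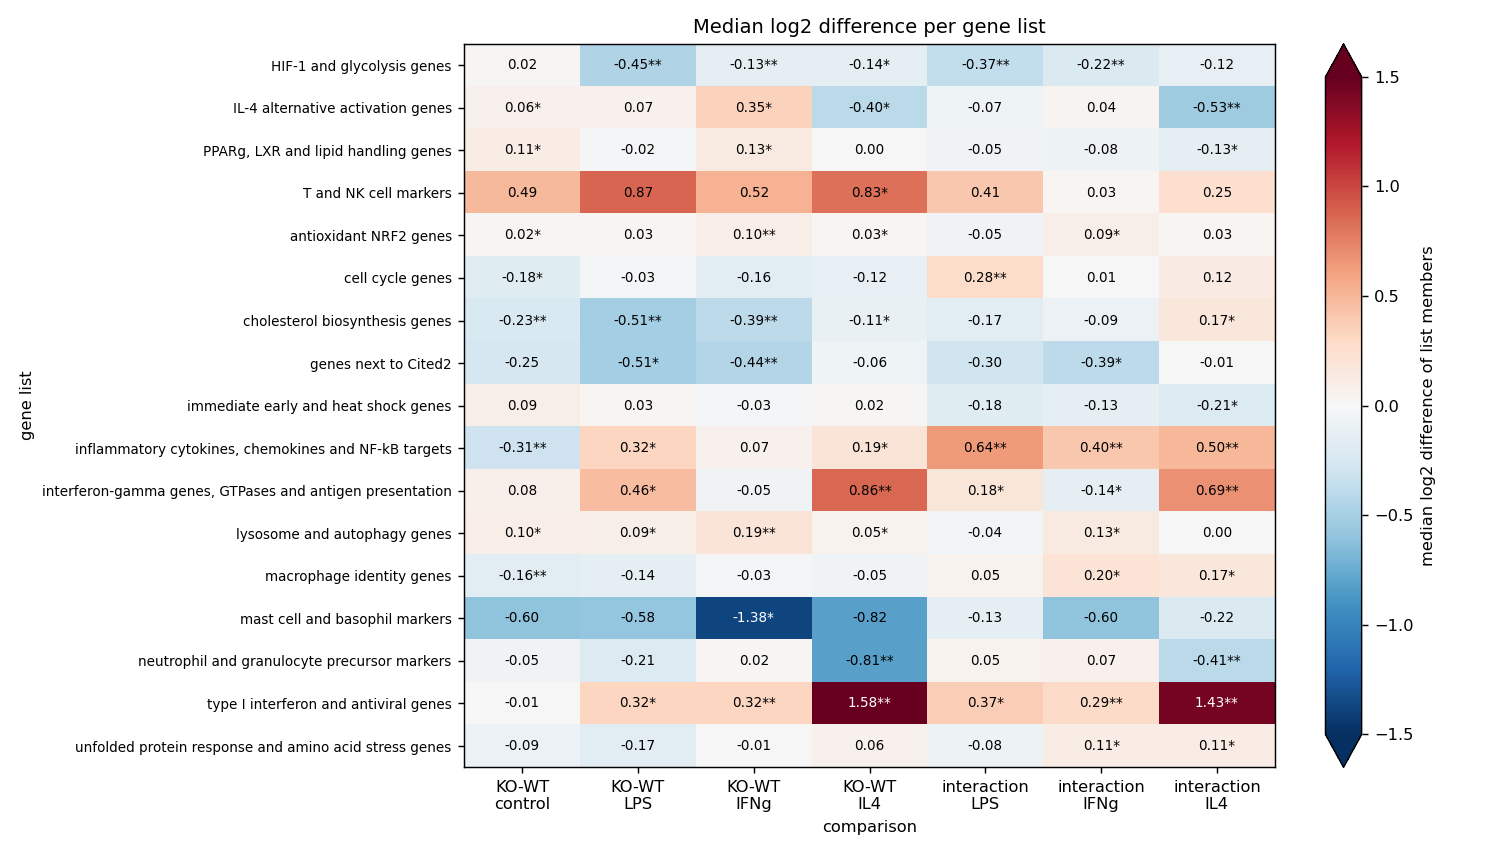
Median log2 difference of the members of each gene list (one list per line of the grid) for KO against WT in each treatment and for the interaction of genotype with each treatment. A single asterisk marks an adjusted p below the threshold by camera, a double asterisk also with an estimated correlation; type I interferon genes with IL4 reached 1.58.

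With IFNg, the interferon-gamma genes did not pass as a group between genotypes, while type I interferon, lysosomal and cholesterol genes did. Of 42 interferon-gamma genes 5 were higher and 9 lower in KO (5 and 11 adjusted over the list alone, median -0.05, adjusted p = 0.24). Gbp2 was 406518 ± 12066 in KO and 409349 ± 17842 in WT and Irf1 61456 ± 508 in KO and 60354 ± 1159 in WT, with log2 differences of -0.01 ± 0.10 and 0.03 ± 0.06 (adjusted p = 1 and 0.9). Cxcl9 was 209273 ± 5759 in KO and 361511 ± 19295 in WT (log2 -0.79 ± 0.30, adjusted p = 0.13, range over the alternatives 2.0e-06 to 0.28). Each KO IFNg value of Cxcl9 lay under each WT IFNg value. Its spread in the fit came from all groups, with 13.5 to 50.9 in KO control. Ciita was 4462 ± 359 in KO and 5289 ± 127 in WT (log2 -0.25 ± 0.09, adjusted p = 0.12; range 0.011 to 0.35). Type I interferon genes were higher in 20 of 36 cases and the other 16 did not pass (24 higher adjusted over the list alone, median 0.32, adjusted p = 4.2e-23). They included the antiviral genes Rsad2, 20329 ± 883 in KO and 8296 ± 805 in WT (log2 1.30 ± 0.09), and Ifi44 (1.24 ± 0.12). Lysosome and autophagy genes were higher in 16 of 30 cases (17 adjusted over the list alone, median 0.19, adjusted p = 2.8e-15), such as the autophagy receptor gene Sqstm1, 23357 ± 1185 in KO and 13717 ± 573 in WT. NRF2 antioxidant genes were higher in 6 of 24 (7 adjusted over the list alone, median 0.10, adjusted p = 4.6e-05), including the cystine transporter gene Slc7a11 (1.35 ± 0.10).
Cholesterol biosynthesis genes were lower in 11 of 24 cases (15 adjusted over the list alone, median -0.39, adjusted p = 4.4e-11), for example Cyp51, 1552 ± 74.9 in KO and 2188 ± 128 in WT. HIF-1 and glycolysis genes fell in 12 of 37 cases and rose in 1 (14 and 1 adjusted over the list alone, median -0.13, adjusted p = 2.3e-04), Pdk1 by -0.74 ± 0.08, with Pfkfb3 the member that rose (0.53 ± 0.06). Genes next to Cited2 fell in 5 of 11 cases (6 adjusted over the list alone, median -0.44, adjusted p = 1.6e-05), among them the interferon gamma receptor gene Ifngr1, 1803 ± 94.9 in KO and 2699.5 ± 153 in WT (log2 -0.58 ± 0.06).
IL-4 alternative activation genes rose in 9 and fell in 5 of 33 cases (10 and 6 adjusted over the list alone, adjusted p = 5.6e-04, or adjusted p = 0.11 with an estimated correlation). Of the mast cell and basophil markers 7 of 7 did not pass over all genes, and 2 fell adjusted over the list alone (median -1.38, adjusted p = 0.019, or adjusted p = 0.12 with an estimated correlation).
Trim12a, at 1352 ± 35.4 in WT, had no read in KO, at least 1308-fold lower, and Gvin1 at least 332-fold, each with KO set at 3 reads over the group. The triglyceride synthesis gene Dgat2 was 85.1 ± 4.09 in KO and 4.34 ± 1.42 in WT, and of 183 immunoglobulin genes 62 were higher and 1 lower in KO. In all, 901 genes were higher and 785 lower in KO (885 and 893 under quantile normalization). With edgeR 2533 genes passed, and with library weights 3512.

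The IFNg response differed by genotype in 466 genes, 246 with a positive and 220 with a negative interaction. Inflammatory genes had a positive one in 12 of 39 cases and a negative one in 2 (17 and 3 adjusted over the list alone, median 0.40, adjusted p = 1.4e-09), such as the chemokine gene Cxcl2 (1.63 ± 0.17) and Nlrp3 (0.65 ± 0.08). A positive interaction need not mean a higher KO level with IFNg, since Nlrp3 and Tnf were lower in untreated KO cells. With IFNg, Tnf averaged 25948 in KO and 27086 in WT, whereas Il6 (75.6 and 42.4), Il1b (148 and 59.8) and Nos2 (35579 and 30009) averaged higher in KO. Among type I interferon genes the interaction was positive in 12 of 36 cases and negative in 1 (23 and 1 adjusted over the list alone, median 0.29, adjusted p = 1.9e-23), led by Cmpk2 (1.06 ± 0.11). Among HIF-1 and glycolysis genes it was negative in 5 of 37 (9 adjusted over the list alone, median -0.22, adjusted p = 7.5e-05), Slc2a1 by -0.61 ± 0.11. Interferon-gamma genes had 3 positive and 5 negative interactions (4 and 7 adjusted over the list alone, median -0.14, adjusted p = 0.013, or adjusted p = 0.39 with an estimated correlation), Irf1 in the latter at -0.49 ± 0.08 (adjusted p = 4.1e-04). Irf1 averaged 2337 in KO and 1639 in WT in control, and 61456 and 60354 with IFNg. Ciita averaged 32.4 in KO and 56.8 in WT in control, and 4462 and 5289 with IFNg. Ciita had an interaction of 0.54 ± 0.13 (adjusted p = 0.026), which 9 of 23 alternatives did not call (adjusted p from 0.0038 to 0.096). Among these were leaving out WT control replicate 1, KO control replicate 3, KO IFNg replicate 1 or any WT IFNg replicate, at adjusted p of 0.09, 0.07, 0.096 and 0.059 to 0.084. Among single genes, Trim30d (3.92 ± 0.32) and the receptor genes Gfra1 (3.59 ± 0.74), Chrm3 (-3.47 ± 0.65) and Robo2 (-3.39 ± 0.75) had the largest interactions by the naming rule beside Gvin1. DESeq2 called 844 genes and library weights 1520.

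With IL4, KO cells carried a broad interferon signature that WT cells lacked at this level. Ifi44 (ENSMUSG00000028037; chromosome 3, 151730922 to 151749960) was 2678 ± 195 in KO and 167 ± 8.49 in WT, a log2 difference of 3.99 ± 0.12 (adjusted p = 4.8e-17). Slfn1, of the interferon-inducible Schlafen family, was 1024 ± 82.2 in KO and 58.1 ± 7.18 in WT. Of 36 type I interferon genes 35 were higher, the same count adjusted over the list alone (median 1.58, adjusted p = 1.5e-107 at the preset correlation). Examples were Ifit3, 1883 ± 73.0 in KO and 178 ± 2.83 in WT, and Rsad2, 3911 ± 334 in KO and 531 ± 8.37 in WT. Interferon-gamma genes were higher in 30 and lower in 4 of 42 cases (32 and 5 adjusted over the list alone, median 0.86, adjusted p = 3.4e-35), among them the guanylate-binding protein genes Gbp3 (2.25 ± 0.08) and Gbp5 (2.2 ± 0.12).
The preset alternative activation markers were lower. Arg1 was 443 ± 24 in KO and 3841 ± 276 in WT (log2 -3.11 ± 0.47, adjusted p = 4.1e-05) and Retnla 20.7 ± 5.05 in KO and 207 ± 8.27 in WT (log2 -3.29 ± 0.34). Chil3 was 9422 ± 792 in KO and 14699.9 ± 246 in WT (log2 -0.64 ± 0.10) and Mrc1 20664 ± 2020.4 in KO and 28366 ± 1114 in WT (log2 -0.46 ± 0.08). Both also averaged lower in untreated KO cells, Chil3 at 362 in KO and 469 in WT and Mrc1 at 4783 and 7346. In the IL-4 alternative activation list 7 of 33 fell and 3 rose (9 and 4 adjusted over the list alone, median -0.40, adjusted p = 0.0034, or adjusted p = 0.25 with an estimated correlation).
Inflammatory genes rose in 12 and fell in 4 of 39 cases (14 and 4 adjusted over the list alone, adjusted p = 0.012, or adjusted p = 0.25 with an estimated correlation). The chemokine gene Ccl5 was 6544 ± 1019 in KO and 2586 ± 256 in WT, and Ccl2 was 82.1 ± 12.5 in KO and 160.2 ± 24.5 in WT. Neutrophil and granulocyte precursor markers fell in 5 of 16 (6 lowered and 1 raised adjusted over the list alone, median -0.81, adjusted p = 2.3e-04), such as S100a9, 95.3 ± 8.92 in KO and 226 ± 27.1 in WT. T and NK cell markers had 1 of 17 raised, the same count adjusted over the list alone (median 0.83, adjusted p = 0.043, or adjusted p = 0.28 with an estimated correlation), and 70 of 183 immunoglobulin genes were higher in KO. In all, 1145 genes were higher and 586 lower in KO. The share higher was 66.1%, and 54.0% under quantile normalization. For IL4 edgeR called 2862 genes, DESeq2 2722 and library weights 4035.

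**Figure D4:**
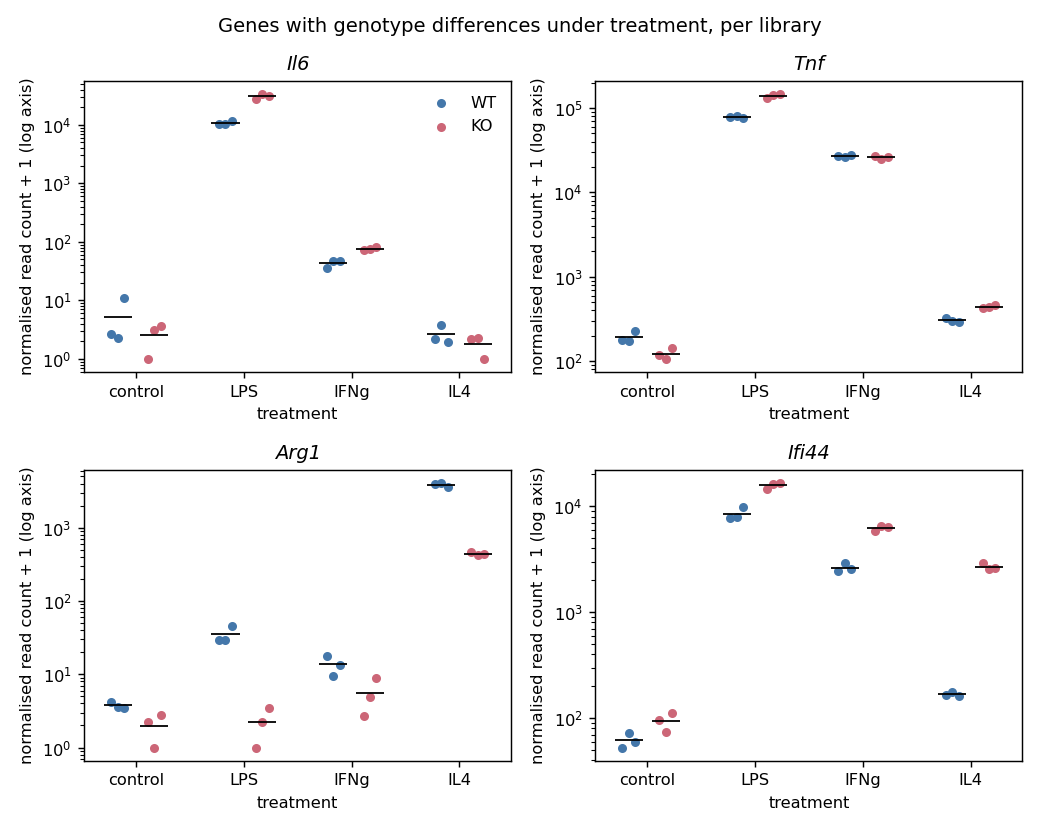
Normalised read counts of Il6, Tnf, Arg1 and Ifi44 in each of the 24 libraries (points; log axis, value plus 1) by treatment and genotype, with bars at the mean of 3 libraries. With IL4, Ifi44 averaged 2678 in KO and 167 in WT, and Arg1 443 in KO and 3841 in WT.

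The response to IL4 differed by genotype in 672 genes, 457 with a positive and 215 with a negative interaction. Type I interferon genes made the clearest group, with a positive interaction in 35 of 36, the same count adjusted over the list alone (median 1.43, adjusted p = 9.9e-135 at the preset correlation). Ifit3 (3.73 ± 0.16), Ms4a4c (3.44 ± 0.19), Ly6a, which encodes the surface protein Sca-1 (3.41 ± 0.28), Ifi44 (3.39 ± 0.17) and Ifit2 (3.37 ± 0.18) had the largest interactions by the naming rule. Interferon-gamma genes had one in 23 of 42 cases (28 positive and 2 negative adjusted over the list alone, median 0.69, adjusted p = 1.3e-39). Inflammatory genes did so in 11 of 39 (16 positive and 1 negative adjusted over the list alone, median 0.50, adjusted p = 1.4e-09), Tnf by 1.19 ± 0.13. IL-4 alternative activation genes had a negative interaction in 8 of 33 cases and a positive one in 1 (12 and 2 adjusted over the list alone, median -0.53, adjusted p = 7.0e-09), such as the transcription factor gene Egr2 (-0.92 ± 0.10) and Flt1 (-1.51 ± 0.20). Retnla had no read in control cells of either genotype, so its interaction of -3.29 (adjusted p from 7.5e-07 to 1 over the alternatives) only restated the difference with IL4. Arg1 had an interaction of -2.08 ± 0.67 that did not pass (adjusted p = 0.1; range 0.00062 to 0.96; 0.037 without KO control replicate 2). Chil3 (-0.27 ± 0.14, adjusted p = 0.48) and Mrc1 (0.16 ± 0.11, adjusted p = 0.67) did not pass either. Neutrophil markers, with a median change of -0.94 by IL4 in WT, had a negative interaction in 3 of 16 cases (6 negative and 1 positive adjusted over the list alone, adjusted p = 8.7e-05). The share of positive interactions was 68.0%, and 56.9% under quantile normalization. DESeq2 called 1169 genes and library weights 2338.

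Averaged over the 4 treatments, the genotypes differed in 4153 genes, 2158 higher and 1995 lower in KO (2040 and 2121 under quantile normalization). Hal (6.58 ± 0.16), Trim34b (4.66 ± 0.34) and Phyhip (4.12 ± 0.22, with no read in WT LPS) were raised most by the naming rule. Trim12a and Gvin1 had no read in 2 and 3 of the 4 KO groups, so their averages of -8.81 and -6.42 depend on the pseudocount. Trim5 (-5.32 ± 0.22), the carbonyl reductase gene Cbr2 (-2.55 ± 0.33), Arg1 (-2.42 ± 0.24) and Rasgrp4 (-2.20 ± 0.15) were among those lowered most beside these and Cited2. All 36 type I interferon genes were higher (median 0.52, adjusted p = 5.3e-49, 36 adjusted over the list alone). Without KO LPS replicate 1 their adjusted p by camera was 1.1e-41, but 0.0015 with an estimated correlation. Without treatment 8 of them were higher and 5 lower (9 and 9 adjusted over the list alone, median -0.01, adjusted p = 0.98), and the median with IL4 was 1.58. Interferon-gamma genes were higher in 28 and lower in 9 of 42 (29 and 9 adjusted over the list alone, adjusted p = 7.1e-12). Cholesterol biosynthesis genes were lower in 18 of 24 cases (19 adjusted over the list alone, median -0.32, adjusted p = 4.2e-10). HIF-1 and glycolysis genes were lower in 18 and higher in 3 of 37 (19 and 4 adjusted over the list alone, adjusted p = 5.4e-05). Lysosome and autophagy genes were higher in 17 and lower in 2 of 30 (17 and 3 adjusted over the list alone, adjusted p = 8.9e-08), while their medians of 0.09 with LPS and 0.05 with IL4 turned to -0.05 and -0.04 under quantile normalization. T and NK cell markers were higher in 8 of 17 cases, the same count adjusted over the list alone (adjusted p = 0.0045, or adjusted p = 0.12 with an estimated correlation). Mast cell and basophil markers were lower in 4 of 7, the same count adjusted over the list alone (adjusted p = 0.019, or adjusted p = 0.12 with an estimated correlation). Of 183 immunoglobulin genes 150 were higher, with the J chain gene Igj at 574 with IL4 in KO and 34.2 in WT. Without KO LPS replicate 1, 5012 genes passed, 2654 higher and 2358 lower.

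Averaged over the treatments, macrophage identity genes were lower in 16 and higher in 6 of 29 cases (16 and 7 adjusted over the list alone, adjusted p = 0.018, or adjusted p = 0.18 with an estimated correlation), with the receptor kinase gene Mertk at 0.67 ± 0.02. NRF2 antioxidant genes were higher in 9 and lower in 2 of 24 (9 and 3 adjusted over the list alone, adjusted p = 0.0036, or adjusted p = 0.12 with an estimated correlation), and their median of 0.03 with IL4 turned to -0.05 under quantile normalization. Genes next to Cited2 were lower in 5 and higher in 1 of 11 (6 and 1 adjusted over the list alone, median -0.33, adjusted p = 0.0013, or adjusted p = 0.067 with an estimated correlation). B cell markers were higher in 4 and lower in 1 of 11, the same counts adjusted over the list alone, with a median of 0.56 that did not pass (adjusted p = 0.068). Neutrophil markers were lower in 7 and higher in 2 of 16, and monocyte and progenitor markers higher in 4 and lower in 2 of 12. Dendritic cell markers were higher in 1 and lower in 2 of 12 and fibroblast and stromal markers higher in 2 and lower in 3 of 17. Adjusted over the list alone these counts were 7 and 2, 4 and 2, 1 and 3, and 2 and 3, and the lists had adjusted p of 0.14, 0.14, 1 and 0.27. CITED family and CBP/p300 partner genes were higher in 7 and lower in 4 of 18, the same counts adjusted over the list alone (adjusted p = 0.14), among them the HIF-2 alpha gene Epas1 (0.44 ± 0.04).
IL-4 alternative activation genes were higher in 12 and lower in 10 of 33 cases (13 and 12 adjusted over the list alone, adjusted p = 0.3). Inflammatory genes were higher in 13 and lower in 9 of 39 (17 and 10 adjusted over the list alone, adjusted p = 0.14). PPARg, LXR and lipid handling genes were higher in 10 and lower in 7 of 30 (10 and 8 adjusted over the list alone, adjusted p = 0.14). Cell cycle genes were lower in 6 and higher in 3 of 35 cases (8 and 3 adjusted over the list alone, adjusted p = 0.27). Immediate early and heat shock genes were lower in 5 and higher in 5 of 26 (the same counts adjusted over the list alone, adjusted p = 0.63). Unfolded protein response genes were lower in 11 and higher in 7 of 25 (12 and 7 adjusted over the list alone, adjusted p = 0.6). Of the mitochondrial oxidative phosphorylation genes 32 of 36 did not pass (adjusted p = 0.8), nor did 8 of 9 mitochondrially encoded genes (adjusted p = 0.85) and 5 of 6 sex-linked genes (adjusted p = 0.93). The median, mean and test of the IL-4, immediate early, unfolded protein response, monocyte, oxidative phosphorylation and mitochondrially encoded lists differed in sign.

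The genotype differences were shared between treatments more than independence would give. Of the genes raised in KO, 436 were raised in both control and IL4 (independent calls would give 47.1), 418 in both control and IFNg (37.0) and 425 in both control and LPS (74.3). Across the 4 treatments 224 genes were raised and 117 lowered in all of them, of 5539 called in any. Another 383 were called in opposite directions in different treatments. These comparisons use different libraries, so the overlaps do not rest on shared control libraries. They may rest on shared animals or cultures, since the labels do not state whether the treatments used separate ones. The counts for independent calls also treat all genes as equally easy to call, so an excess over them does not measure a shared effect of CITED2 loss.

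Whether loss of CITED2 shifts the response as a whole was addressed with the genes each treatment changed, taken as sets. The 2728 genes raised by LPS, chosen on the average of both genotypes, had a median KO minus WT log2 difference of 0.09 with LPS, where random sets of matched expression had -0.04 (95% of sets from -0.06 to -0.02). Of them 718 were higher and 343 lower in KO. Without KO LPS replicate 1 the median was 0.15. The 3774 genes lowered by LPS had a median of -0.31 with LPS (random sets -0.14), with an SD of 0.32 between the medians of the KO libraries. It was -0.16 under quantile normalization and -0.13 without KO LPS replicate 1. For the 2103 genes raised by IFNg the median was -0.038 with IFNg (random sets -0.02; -0.024 without KO IFNg replicate 1), with 223 higher and 238 lower. For the 2466 genes lowered by IFNg it was -0.062 with IFNg (random sets -0.053; -0.027 without WT IFNg replicate 3), with 190 higher and 102 lower, and it was 0.01 under quantile normalization. For the 732 genes raised by IL4 it was 0.07 with IL4 (random sets 0.00; 0.11 without KO IL4 replicate 2), with 187 higher and 75 lower. For the 502 lowered by IL4 it was -0.12 (random sets -0.03; -0.053 without WT IL4 replicate 1 and -0.195 without KO IL4 replicate 2).

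**Figure D5:**
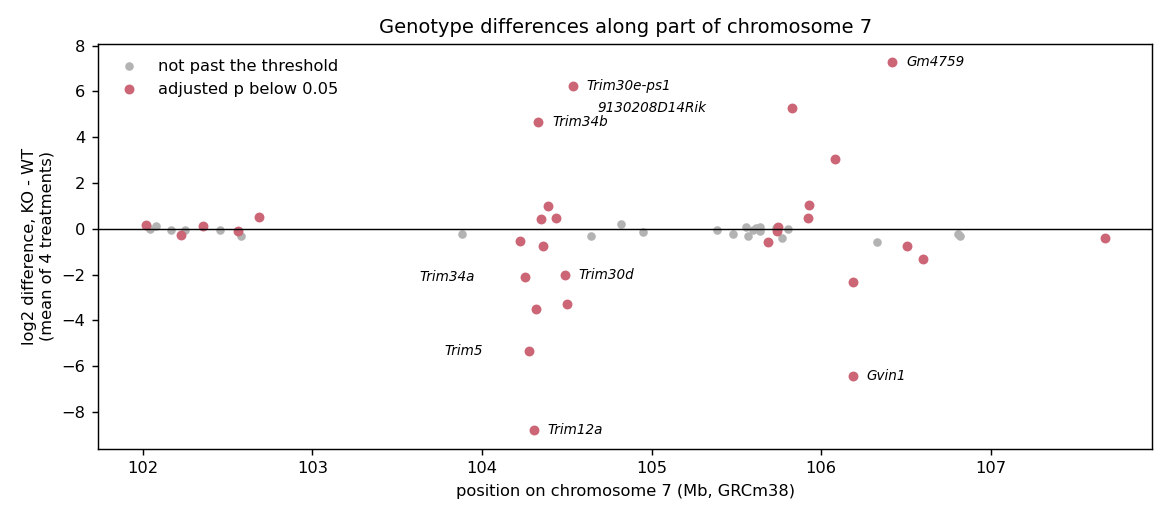
Log2 difference between KO and WT (mean of the 4 treatments) of genes along GRCm38 chromosome 7, by position in megabases. Trim12a lies lowest, at -8.81, and Gvin1 at -6.42, sizes that depend on the pseudocount, since 2 and 3 of the 4 KO groups held no read of them.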

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

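The results here are differences between genotypes in the response to a treatment, found by a test of the interaction itself. The tests of strain haplotypes, paralog reads, carried-over reads and scaling, and the repeat of the split counts without the shared genotype difference, were chosen only after the results were seen.

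For LPS the interaction passed for 1639 genes. A positive interaction means that the change from control had a higher value in KO. It can come from a lower KO level in control without a higher one under treatment, as for Ciita with IFNg. The interaction of Gvin1 was negative (-4.66; no read in untreated KO cells, so the size depends on the pseudocount), as were those of Lad1 (-4.39) and Arhgef10l (-3.99), while those of Pax4 (4.61), Trim30d (4.60), Il6 (2.35), Nos2 (1.57) and Tnf (1.49) were positive. Pax4 had no read in control cells of either genotype, so its value only restates the difference with LPS. Il6 had 0 to 4 reads per control library and Nos2 6 to 26. Without KO LPS replicate 1, Lad1 moved to -2.89 and Arhgef10l to -3.0. The adjusted p of Gvin1 ranged from 1.2e-06 to 0.92 over the alternatives, of Pax4 from 0.00023 to 1 and of Lad1 from 2.7e-05 to 0.13, with the highest values from edgeR or, for Lad1, from a fit of only the compared groups. Among lists, inflammatory genes (median 0.64), type I interferon genes (0.37), cell cycle genes (0.28) and interferon-gamma genes (0.18) had positive interactions, and HIF-1 and glycolysis genes (-0.37) negative ones. The type I interferon and interferon-gamma lists lost their call with an estimated correlation.

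For IFNg the interaction passed for 466 genes. Gvin1 (-4.69), Chrm3 (-3.47), Robo2 (-3.39) and Irf1 (-0.49) had negative interactions, and Trim30d (3.92), Gfra1 (3.59) and Ciita (0.54) positive ones. Gvin1 had no read in either KO group, and its adjusted p ranged from 4.5e-08 to 1 over the alternatives. Inflammatory genes (median 0.40), type I interferon genes (0.29), macrophage identity genes (0.20), lysosome genes (0.13), unfolded protein response genes (0.11) and NRF2 genes (0.09) had positive interactions, and genes next to Cited2 (-0.39), HIF-1 and glycolysis genes (-0.22) and interferon-gamma genes (-0.14) negative ones. Of these, the macrophage identity, lysosome, unfolded protein response, NRF2, interferon-gamma and Cited2 neighbour lists lost their call with an estimated correlation.

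For IL4 the interaction passed for 672 genes. Ifit3 (3.73), Ms4a4c (3.44), Ly6a (3.41), Ifi44 (3.39) and Ifit2 (3.37) had positive interactions, and Retnla (-3.29) a negative one. Retnla had no read in control cells of either genotype, so its value only restates the difference with IL4 (adjusted p from 7.5e-07 to 1 over the alternatives). Type I interferon genes (median 1.43), interferon-gamma genes (0.69), inflammatory genes (0.50), cholesterol genes (0.17), macrophage identity genes (0.17) and unfolded protein response genes (0.11) had positive interactions, and IL-4 alternative activation genes (-0.53), neutrophil markers (-0.41), immediate early genes (-0.21) and PPARg, LXR and lipid genes (-0.13) negative ones. The cholesterol, macrophage identity, unfolded protein response, immediate early and lipid lists lost their call with an estimated correlation.

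Splits of the libraries other than by genotype were counted for each number of called genes. For the average over treatments, 1 of 100 splits called as many genes as the real 4153, the real one itself, and the highest other called 685. That excludes a chance arrangement only if libraries of different treatments came from separate animals or cultures, which the labels do not state. The splits for the interactions rest on the same condition. Each comparison of 3 with 3 libraries had 1 of 10 splits as large, the real one, too few splits for a share under 0.05. There the real counts and the highest other were 1334 and 3 in control, 4141 and 669 with LPS, 1686 and 1 with IFNg, 1731 and 0 with IL4, 9942 and 3 for LPS in WT, 8412 and 1 for IFNg in WT, and 3749 and 0 for IL4 in WT. For the interactions, 5 of 100 splits called as many genes with LPS (real 1639, highest other 1896), 7 with IFNg (466 and 923) and 4 with IL4 (672 and 868). The share thus reached 0.05 for LPS and IFNg and stayed under it for IL4. These shares cannot decide on chance in any of the treatments. The other splits as large, 4, 6 and 3 of them, mostly exchanged the genotypes within 1 treatment, which turns the shared genotype difference into an interaction. After removal of that shared difference 1 of 100 splits was as large in each case, with 1641 genes and 1420 in the highest other for LPS, 465 and 4 for IFNg, and 671 and 26 for IL4.

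Genes with the largest genotype differences lay close together on chromosomes 7 and 10, among them Trim12a, Trim5, Trim30d and Gvin1, and Hal and Amdhd1. Reads moving between Trim paralogs are argued against in control cells for the called genes. There the 2 Trim genes called higher gained 2.21% of what the 5 called lower lost (34.7 against 1569 in value). Genes not called were left out of the sums. Of these Trim12c (826 in WT, 967 in KO) and Trim3 (762 and 903) were higher in KO, and Trim30a (2486 and 2264), Trim6 and Trim30c were lower or level. The test did not cover Gvin1 and its neighbours. With treatment the largest gain was 381% of the loss (LPS; 39.3% with IFNg and 304% with IL4), which leaves such reads open there. A difference in strain haplotypes may contribute. Of the 40 genes left with 1 per tandem family, 40% had another within 5 Mb, above the bound of random sets (35%). Each predicted gene counted there as a family of its own, so that Gm18853, which lies within Gvin1, counted as its neighbour. The 40% thus includes neighbours within the same locus. Without predicted genes 28.6% lay under the bound of random sets (32.1%). Haplotype and deletion cannot be told apart, since each genotype is confounded with its mice, and an effect of CITED2 loss itself remained untested.

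Immunoglobulin genes were higher in KO in every treatment: 150 of 183 on average, with a median log2 difference of 1.81, positive also under quantile normalization and median centring. Their summed value rose from 1806 ± 103 in WT to 6375 ± 525 in KO control cells and from 533 ± 49.5 to 4296 ± 34.6 with IL4, while Ighm fell in control. Plasma cells in the KO cultures are a candidate source. Of 15 plasma cell markers, 2 of them also B cell markers and 8 at a WT mean of at least 10, the 7 others had a median difference of 0.40 (SE 0.408), with Mzb1 (2.26), Pou2af1 (2.23) and Cd79a (1.94) higher and Tnfrsf17 (0.40), Eaf2 (0.16), Derl3 (0.05) and Fcrl5 (-0.04) not past. A few cells cannot be told apart from another source at such levels.

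Interferon genes were higher in KO with IL4, 35 of 36 on the type I list. Reads carried over from LPS libraries are argued against: Il6, Il1b, Nos2, Tnf and Ptgs2 gained a median of 0.0903% of their KO LPS level (at most 0.114%), where the raised type I genes gained 6.45%. The authors' scaling is argued against too, since 35 of 36 were called higher both with quantile normalization and with median centring. An effect of the genotype itself and differences between the mice or cultures of the genotypes remained open and untested.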

How the results depend on the processing

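The edgeR and DESeq2 fits, library weights and the fits of lists and named genes without KO LPS replicate 1 were chosen after seeing the data. Over the alternatives, 168 pairs of a named gene and a comparison gave 3303 values. Of these 3189 were counted as unchanged, 86 lost the call, 28 gained one and 0 reversed a call of the main fit. A pair not called in the main fit whose sign changed was counted as unchanged, whatever its adjusted p. The changed values lay in 34 pairs. Of 95 list calls by camera, 45 held and 50 were lost with an estimated correlation, which allows for more dependence between genes. Of the counts and medians, 260 stayed within 1.5 times or the spread and 31 moved, as follows.

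Library weights, which lower the influence of variable libraries, gave 3063 genes in control, 3512 with IFNg, 4035 with IL4, 6125 for IL4 in WT, and 2755, 1520 and 2338 for the interactions with LPS, IFNg and IL4. A fit of only the compared groups gave 1021 genes with LPS and 862 for the LPS interaction. For IFNg, edgeR called 2533 genes, 2585 without KO LPS replicate 1, and DESeq2 2588. For IL4 these were 2862, 2895 and 2722. DESeq2 called 844 and 1169 genes for the interactions with IFNg and IL4. The cause was not tested for these. Requiring an absolute log2 fold change of at least 1, which by construction calls fewer genes, left 316 in control, 1158 with LPS, 330 with IFNg, 444 with IL4, 545 on average, 5627, 4084 and 986 for LPS, IFNg and IL4 in WT, and 349, 72 and 172 for the interactions. For genes raised by a log2 of at least 2, the median difference was -0.069 with IFNg and 0.014 with IL4, and for those lowered as much -0.017 and -0.15. The cause was not tested.

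Leaving out 1 library, the counts ranged from 1008 to 1113 in control, 3217 to 5038 with LPS, 1263 to 1441 with IFNg and 1241 to 1718 with IL4. The median of genes raised by IL4 ranged from 0.054 to 0.108. With the replicate block the counts were 1257, 3984, 1607 and 1644 in the 4 treatments and 4000 on average. Whether the numbers pair samples was checked after removal of group means. Libraries of equal number correlated across genes between genotypes at 0.02, -0.26 and -0.39 in control, -0.01, -0.1 and -0.1 with LPS, and 0, -0.15 and 0.11 with IL4. With IFNg these were 0.35, 0.36 and 0.08. There 5 libraries correlated best with their own number, against 1 in control, 0 with LPS and 2 with IL4. Pairing of KO with WT libraries, or a batch they share, is thus not excluded for IFNg, while the other treatments showed no sign of it. Whether libraries of different treatments within a genotype came from the same mouse or culture was not tested. The averages over treatments and the interactions treat them as independent.

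Depth limits genes of low value with LPS, since KO LPS replicate 1 had no read for 7441 of 18637 genes. In simulated data made from these libraries, limma recovered 80% of genes changed by a log2 of 1 and 93% of those changed by 2 with LPS, 84% of both in control and 77% and 84% with IFNg. Changes were planted only in genes above a minimum mean value, so these shares say nothing about genes of low value. Of the limma calls 24.5%, 9.68% and 4.73% were false, with 200 changed genes simulated where the real LPS comparison called 4141. Without KO LPS replicate 1 that share was 19.5% with LPS, and with edgeR on all libraries 9.0%.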

Other observations

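Gene families were chosen after their values were seen. Classical and related MHC class I genes (H2 family, 19 measured) were higher in KO in 11 cases in control, 9 with LPS, 9 with IFNg and 12 with IL4, and in 14 on average. Guanylate-binding protein genes, which act against intracellular pathogens, were higher in 9 of 9 cases with IL4 (median 2.26) and in 7 with LPS. Their median with IFNg was 0.00, or -0.06 under quantile normalization. The Ifi200 family of nucleic acid sensors was higher in 5 of 9 cases in control, 6 with LPS, 4 with IFNg and 8 with IL4 (median 1.88). Schlafen genes were higher in 3, 5, 4 and 8 of 9 cases, though their median turned to -0.01 in control and -0.04 with LPS under quantile normalization. In the Ms4a family of membrane proteins, 4 of 13 genes were lower in control and 6 higher with IL4.

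In KO LPS replicate 1, Trim12a had 8 reads, 6.01% of the 133 that the WT LPS level would give at its depth, and Cited2 had 4, or 2.63% of 152. Gvin1 had 0 reads there, where 18.6 would be expected at the WT level. Xist was expressed in all groups, at 14426 ± 1796 in WT control and 13452 ± 1136 in KO control cells. The J chain gene Igj, which joins immunoglobulin chains, stood at 574 in KO and 34.2 in WT with IL4. The alpha heavy chain gene Igha stood at 2256 ± 316 in KO and 189.7 ± 35.6 in WT control cells.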
